A study of Homo sapiens with 4 samples.

How the data were processed

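RNA from stably transduced, puromycin-selected CL1-0 and CL1-5 cells was extracted with a column kit, converted to biotin-labelled cRNA and hybridised to 1-colour Affymetrix human arrays, per the labels' protocols. There were 4 arrays in 4 groups, each with 1 array, and the groups were taken from the titles of the arrays. The deposited values are linear-scale intensity, 1 signal per probe set, already scaled between arrays by the authors. The submitters' processing notes name MAS5 with no version. Target value, background step and scanner settings are not given in the sources used here. The lowest signals, 4.22 to 4.49, and the nearly coinciding quantiles would also fit a multi-array summary turned back to a linear scale, so the summary algorithm is not settled. A multi-array summary compresses differences of dim probe sets, and MAS5 gives noisier ones, so small folds of dim genes depend on which was used.

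Each array held 54675 probe sets. The 2%-trimmed means of the arrays were 222.1 (CL1-0 vector control), 222.8 (CL1-0 ALDOA overexpression), 221.7 (CL1-5 non-silencing control) and 219.4 (CL1-5 ALDOA knockdown). They lay within 1.55% of one another, under the limit of 5% fixed before the data were examined, so the deposited signals were used without further scaling. The floor of each array was its 40th percentile, a signal of 30.5 to 31.9, and lower signals were raised to it. A gene was measured in a comparison if its higher array reached that array's 60th percentile, 71.5 to 73.5. A difference with 1 array at the floor is a lower bound and is written as at least so many fold. For arrays, their number limits the precision, and signal over background limits which genes can be read.

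Probe sets were named from the platform's annotation, in which 41091 probe sets had 1 gene symbol, 1801 had several and 11721 were not named here, beside 62 control probe sets. Of the probe sets with 1 symbol, 41037 had a gene identifier found in the RefSeq gene table of assembly GRCh38.p14, which changed 0 symbols. The sources used here name no genome build for the array, so no coordinates are given. Probe sets with several symbols were not used for genes, and 58 probe sets of XIST and Y-linked genes were left out, which left 19741 genes. A gene's value was its probe set with the highest mean log2 signal over the 4 arrays, and the range over its other measured probe sets was kept to show disagreement.

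The differences computed were ALDOA overexpression against vector control in CL1-0, ALDOA knockdown against non-silencing control in CL1-5, both of these together, and the CL1-5 control against the CL1-0 control. Each is a difference of log2 signals, and genes at least 2-fold apart were counted. With 1 array per group no test across cultures exists and no p-value was computed. As a yardstick of technical disagreement, the SD of log2 differences among measured probe sets of the same gene was pooled over genes. The overexpression and knockdown comparisons share no array. The subline comparison shares an array with each of them, so it was not correlated or overlapped with them.

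Before the data were examined, 43 gene lists with 827 members were fixed, of which 749 had a usable probe set. A list's median log2 difference was placed among 10000 random lists of the same size, matched on mean expression in 20 bins and drawn with replacement, and was called apart at or below percentile 2.5 or at or above 97.5. Lists with fewer than 5 measured members were not placed, and ALDOA was left out of every list. Random lists treat genes as independent, so the percentile describes these arrays and is not a test across cultures. The genes named were fixed by a rule: in each comparison the 10 furthest higher and 10 furthest lower with both arrays above the floor and all measured probe sets pointing the same way, up to 4 members with the largest difference per list described, the 10 genes of each direction that differed oppositely in both ALDOA comparisons, and 11 genes always named. Of these 11, 2 had no usable probe set and were not analysed here. Genes named outside the rule, such as ISG15 as a list example, were chosen after their values were seen, and so were the mitochondrially encoded genes as a group.

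The 8 alternatives fixed beforehand were quantile normalization, cyclic loess normalization, median scaling, floors at the 20th and 60th percentiles, no filter and no floor, the mean of all probe sets of a gene, and leaving out probe sets of the classes that can bind several transcripts. A further 2 for the correlation were added after seeing the data. The calculations were tested on simulated data built from these arrays. Of 100 genes planted at a log2 difference of 1.5, 97 passed 2-fold in the overexpression step and 97 in the knockdown step, each run on 19741 genes. Of 100 planted at 0.7, 4 passed in the overexpression step and 9 in the knockdown step. Of 38 lists without a planted difference, 2 were called in the overexpression step and 4 in the knockdown step. The planted genes all had a control signal above the filter, and the simulated noise had the same SD at every signal. Recovery of dim genes was therefore not tested. The noise was also drawn independently for each gene. These counts therefore do not show how often lists of co-regulated genes would be called between cultures. Normalization used limma 3.58.1 in R 4.3.3, and all else Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.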

Results

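Gene expression was measured on 4 arrays of RNA from CL1-0 and CL1-5, sublines of an established human lung adenocarcinoma cell line, of which CL1-5 is known as the more invasive. In CL1-0 the pair of arrays held cells carrying a vector control and cells overexpressing ALDOA, the glycolytic enzyme aldolase A. In CL1-5 the pair held cells with a non-silencing short hairpin RNA and cells with a hairpin against ALDOA. Each of the 4 groups had 1 array, so no difference below has a replicate check and no p-value is given. Genes are not replicates of a culture, and the number of arrays limits the precision of every value. The 54675 probe sets had a median signal of 46.6 in the CL1-0 vector control, 46.0 with ALDOA overexpression, 47.1 in the CL1-5 non-silencing control and 47.5 with ALDOA knockdown. Across all probe sets the log2 signals correlated at r = 0.994 between the CL1-0 arrays and at r = 0.993 between the CL1-5 arrays. Between arrays of different sublines r lay from 0.945 to 0.948. The ratio of 3' to 5' signal was 1.06 to 1.08 for GAPDH and 1.21 to 1.36 for ACTB, the transcripts used as RNA quality controls.

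The level of ALDOA itself was examined first, as a check of the labels. The brightest ALDOA probe set had a signal of 8630 in the CL1-0 vector control and 12255 with overexpression, which was 1.42-fold higher (log2 difference 0.51). In CL1-5 its signal was 11385 in the non-silencing control and 7178 with knockdown, 1.59-fold lower (-0.67). All 3 ALDOA probe sets differed in the labelled direction. Their mean log2 difference was 0.61 ± 0.17 (SD over 3 probe sets) in CL1-0 and -0.85 ± 0.28 in CL1-5, a spread between probe sets and not between cultures. The dimmest probe set had signals of 885, 1548, 1208 and 538 in the vector control, overexpression, non-silencing control and knockdown, log2 differences of 0.81 and -1.17. All 3 belong to a class of probe sets that can also bind related sequences, so signal from ALDOA pseudogenes or paralogs stays uncertain. ALDOC, which encodes the brain-type aldolase, was lower in both perturbed arrays, at -0.49 with ALDOA overexpression and -0.84 with ALDOA knockdown. Of 20 measured glycolysis genes other than ALDOA, 15 were lower with knockdown and 5 higher (median -0.26), with HK2 at -0.89. The lower ALDOA signal there therefore cannot by itself be told apart from that shift.

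**Figure D1:**
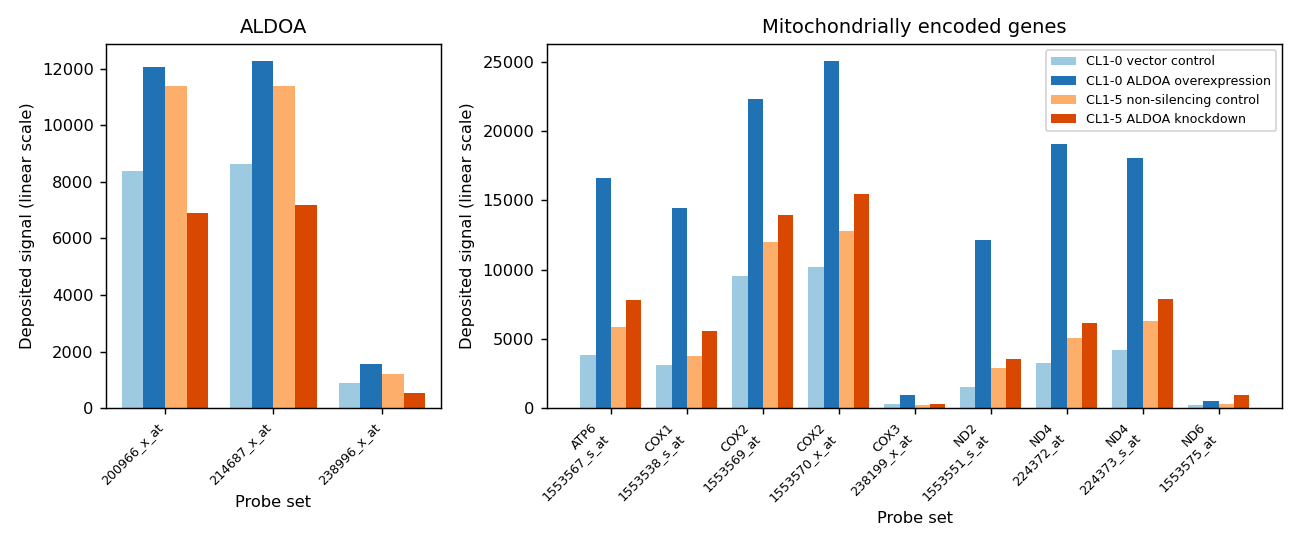
Deposited signal on a linear scale (vertical axis) for each probe set (horizontal axis) of ALDOA, left, and of the mitochondrially encoded genes above the floor on every array, right, with 1 bar per array and no error bars because each group had 1 array. The 3 ALDOA probe sets were higher with overexpression and lower with knockdown, and each mitochondrial probe set was highest in the overexpression array except that of ND6, whose signal was 528 there and 944 in the knockdown array.

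ALDOA overexpression in CL1-0 was compared with the vector control to find the genes that differed with more ALDOA. Few genes reached a 2-fold difference. Of 11313 measured genes, 10 were at least 2-fold higher and 28 at least 2-fold lower. The higher count was 18 with no filter and no floor and 21 without the probe sets that can bind several transcripts, and the lower count was 6 with the mean of all probe sets per gene. Of the 10 higher genes, 7 are encoded by mitochondrial DNA and form the respiratory chain: ND2 (log2 difference 3.01), COX1 (2.21), ATP6 (2.12), ND4 (2.11), COX3 (1.68), ND6 (1.30) and COX2 (1.29). COX1 signal was 3122 in the vector control and 14448 with overexpression. The other genes were PTPRO, a receptor-type tyrosine phosphatase (3.51), the locus annotated MIRLET7D (1.31) and VMP1, an autophagy protein (1.03). The PTPRO value rested on 1 probe set, and the other PTPRO probe sets lay below the floor on both CL1-0 arrays. Nuclear genes of oxidative phosphorylation did not share the difference, with a median of -0.03 over 29 measured members, inside the range of -0.05 to 0.05 that held the middle 95% of random lists.

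Among genes above the floor on both arrays whose probe sets pointed the same way, the furthest lower with overexpression was TMEFF2, a transmembrane protein with follistatin-like domains (-2.39), with a signal of 187 in the vector control and 36 with overexpression. DDIT4, a stress-induced inhibitor of mTOR signalling, followed at -1.41. Next were ZNF204P (-1.27), TMEM170B (-1.26), the proteoglycan SRGN (-1.23), SEL1L3 (-1.20), BTN3A2 (-1.20), the adhesion molecule ICAM4 (-1.15), HINT3 (-1.14) and SH3PXD2A, an invadopodium scaffold (-1.14). Overexpression signals were close to the floor of 30.5 for BTN3A2 (35), TMEFF2 (36) and SEL1L3 (42), so their sizes depend on where the floor is set. The other HINT3 probe sets gave -0.71 and -0.09. Differences among all measured genes had an SD of 0.267 on the log2 scale, and the middle 95% lay from -0.56 to 0.51. Probe sets of the same gene differed from one another by an SD of 0.23.

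Of 39 gene lists with enough measured members, 13 had medians outside the range of random lists in the overexpression comparison, 5 higher and 8 lower, where 2.0 would be expected by chance and 2 of 38 lists without a planted difference were called in simulated data. The chance and simulated counts take genes as independent, and some lists share members. They are therefore no measure of how lists vary between cultures. Targets of hypoxia and HIF1 were lower, with 16 of 21 members below the vector control and a median of -0.29 (random lists -0.10 to 0.10). Examples were ANKRD37 (-1.46), whose other probe set gave 0.18, DDIT4 (-1.41), the oxygen sensor EGLN1 (-0.81) and the mitophagy receptor BNIP3L (-0.79). Glycolysis genes were lower by less, with 15 of 19 members below control and a median of -0.11 (random lists -0.07 to 0.08). Those with the largest differences were PFKFB4 (-1.12), whose other probe set gave 0.06, the hexokinase HK2 (-0.64), ALDOC (-0.49) and the glucose transporter SLC2A1 (-0.38). Other members lay near the control, among them GAPDH (-0.015), ENO1 (-0.053), PKM (-0.041) and TPI1 (0.061). Immediate early and ERK feedback genes were higher, with 14 of 15 members above control and a median of 0.28 (random lists -0.14 to 0.13). They included the phosphatase DUSP4 (0.85) and the feedback inhibitor SPRY4 (0.46). TGF-beta targets had a median of 0.19 over 11 members, 7 higher and 4 lower. The highest were ID3 (0.80), ID1 (0.51) and ID2 (0.46). The lower ones were the receptor TGFBR1 (-0.60), LTBP1 (-0.51), PMEPA1 (-0.42) and CCN2 (-0.17).

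All 8 measured members of the inflammatory cytokine and NF-kB list were above control (median 0.20, random lists -0.26 to 0.20), among them LIF (0.74) and ICAM1 (0.52). Antigen presentation lists were lower, MHC class I at a median of -0.20 with 9 of 12 members below control and MHC class II at -0.50 with 5 of 5. HLA-DMA was at -0.85, HLA-DPA1 at -0.76 and HLA-B at -0.37. Of 13 mesenchymal genes 12 were below control (median -0.17), with AXL at -0.58 and FN1 at -0.44, and of 9 epithelial genes 7 were below control (median -0.27), with PKP3 at -0.53 and KRT8 at -0.41. Fatty acid synthesis (median -0.22, ACSL4 -0.94) and cholesterol synthesis (-0.15, STARD4 -0.60) were lower as well. Proteasome subunits (0.07, with 19 of 24 members above control) and splicing factors (0.08, with 17 of 21) were slightly higher. The inflammatory list lost its place outside the random range under 4 alternative settings, with medians of 0.21 under quantile normalization, 0.19 under cyclic loess, 0.09 with the floor at the 60th percentile and 0.06 with the mean of all probe sets. Calls were also lost under 2 settings for the proteasome (0.07 and 0.02), mesenchymal (-0.11 and -0.17) and MHC class I lists (-0.10 and -0.09), and under 1 for the epithelial (-0.10) and splicing lists (0.10).

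ALDOA knockdown in CL1-5 was compared with the non-silencing control to find the genes that differed with less ALDOA. Genes of the type I interferon list and of the inflammatory cytokine and NF-kB list were lower, with 13 and 6 members at least 2-fold below control. Of 11305 measured genes, 46 were at least 2-fold higher and 118 at least 2-fold lower, 7 of these 164 with 1 array at the floor. Among genes above the floor on both arrays with agreeing probe sets, the furthest lower was MX1, an interferon-induced antiviral GTPase (-3.17), whose signal was 383 in the non-silencing control and 43 with knockdown. The next were PAEP, which encodes glycodelin (-2.90), the granzyme B inhibitor SERPINB9 (-2.79), COXFA4L3 (-2.75), NAV2 (-2.60), the cytokine IL1B (-2.58), IFI6 (-2.57), the survival factor BCL2A1 (-2.31), the NF-kB regulator NFKBIZ (-2.31) and IFI27 (-2.21). The NAV2 probe sets disagreed in size, with other measured ones at -0.20 and -0.43. Without the probe sets that can bind several transcripts NAV2 was not measured, since those left lay below the floor on both arrays.

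By the same criteria, the genes furthest higher with knockdown were the adhesion molecule AMIGO2 (2.62), ID4, an inhibitor of DNA binding by helix-loop-helix factors (2.61), and the secreted Wnt antagonist DKK1 (2.54). AMIGO2 signal was 444 in the non-silencing control and 2736 with knockdown. They were followed by HOPX (1.81), the YAP target ANKRD1 (1.80), the zinc exporter SLC30A1 (1.79), the kinase NUAK1 (1.75), mitochondrially encoded ND6 (1.51), DOCK10 (1.45) and the motor protein MYO5B (1.43). Control signals were close to the floor of 31.7 for NUAK1 (36) and ID4 (43), so their sizes depend on where the floor is set. Differences among all measured genes had an SD of 0.319, and the middle 95% lay from -0.71 to 0.54. Probe sets of the same gene differed by an SD of 0.22.

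Of 38 lists placed against random lists in the knockdown comparison, 15 lay outside the range, 7 higher and 8 lower, where 1.9 would be expected by chance and 4 of 38 lists without a planted difference were called in simulated data. Again the chance and simulated counts take genes as independent. All 17 measured members of the type I interferon list were below the non-silencing control, 13 of them at least 2-fold, with a median of -1.41 (random lists -0.15 to 0.14). ISG15 was at -1.10, and OAS1 was at least 4.57-fold lower because its knockdown signal was at the floor. All 16 measured members of the inflammatory cytokine and NF-kB list were also below control (median -0.79, random lists -0.15 to 0.13), including IL1A (-1.62), TNFAIP3, a feedback inhibitor of NF-kB (-1.60), and CXCL1 (-1.33). MHC class I genes followed with 12 of 13 members below control and a median of -0.64. The immunoproteasome subunits PSMB9 (-2.05) and PSMB8 (-1.41) and the peptidase ERAP1 (-1.03) had the largest differences.

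Hypoxia and HIF1 targets were lower with knockdown in 20 of 24 members, 6 of them at least 2-fold, with a median of -0.68 (random lists -0.10 to 0.09). The prolyl hydroxylase EGLN3 was at -2.18, VLDLR at -1.43, the repressor BHLHE40 at -1.14 and the mitophagy receptor BNIP3 at -1.13. Glycolysis genes were lower in 15 of 20 members (median -0.26, random lists -0.08 to 0.09), with the enolase ENO2 at -1.16, PFKFB4 at -1.12 and HK2 at -0.89. GAPDH (-0.025), ENO1 (0.054), PKM (0.065) and TPI1 (0.10) lay near the control. Mitosis genes were lower in 21 of 24 members (median -0.27), led by HMMR (-0.77), CENPF (-0.62) and MKI67 (-0.52). DNA replication genes were higher in 16 of 24 (median 0.11), with E2F1 at 0.58 and CCNE1 at 0.47. In the immediate early and ERK feedback list 17 of 20 members were lower (median -0.12), among them EGR1 (-1.98), FOS (-1.35) and DUSP6 (-1.19). Fatty acid synthesis had a median of -0.23, with the desaturase SCD at -2.07.

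Mesenchymal genes were higher with knockdown in 15 of 18 members (median 0.22, random lists -0.12 to 0.11), among them CCN2 (0.89), COL5A1 (0.87) and AXL (0.75). Matrix metalloproteinases and their inhibitors were higher in 11 of 16 (median 0.22), with MMP2 at 0.86 and ADAMTS1 at 0.84. YAP targets were higher in 11 of 14 (median 0.23). NRF2 targets (median 0.14, the cystine transporter SLC7A11 at 1.42), amino acid response genes (0.13) and proteasome subunits (0.14, with 19 of 24 members higher) were also above the random range. The amino acid response list left the called range under 3 alternative settings (medians 0.09 to 0.11), DNA replication under 2 (0.09 and 0.05) and the metalloproteinase list under 1 (0.12). With the mean of all probe sets per gene, the count of genes at least 2-fold higher was 28.

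**Figure D2:**
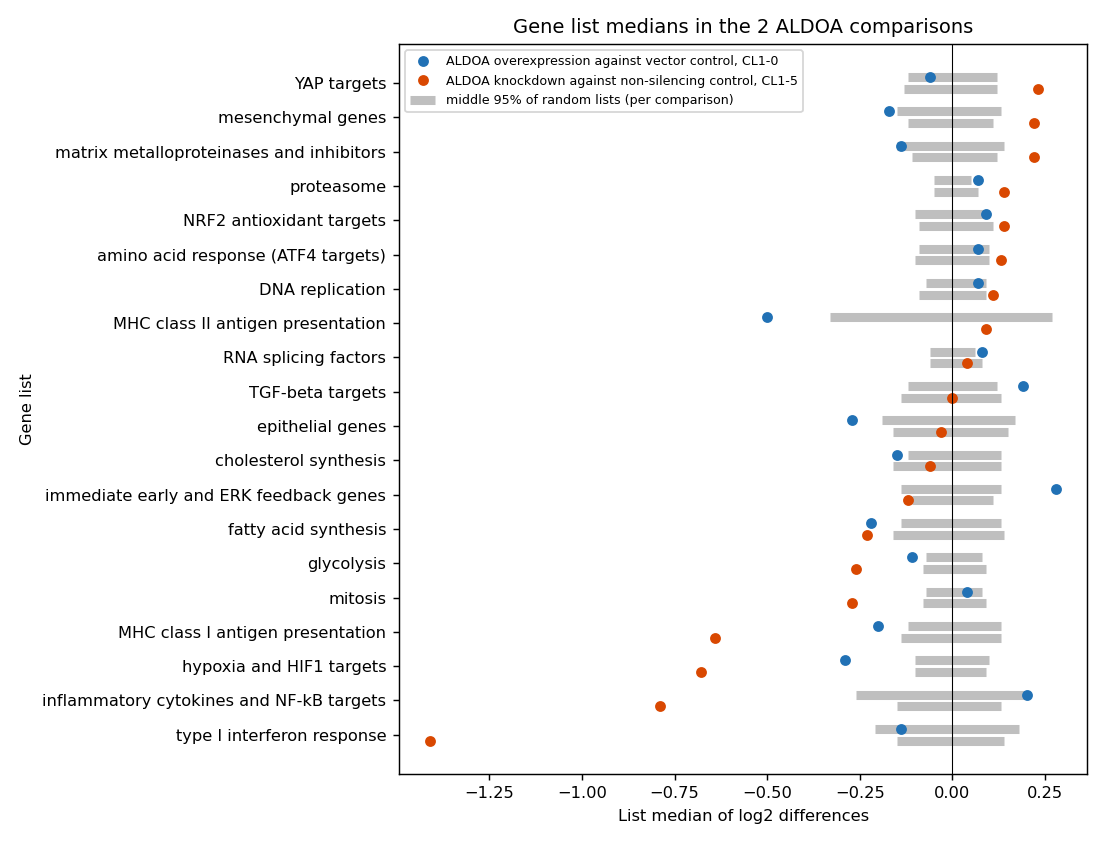
Median log2 difference of each gene list (horizontal axis) for the lists outside the random range in at least 1 of the ALDOA comparisons (vertical axis), with blue points for overexpression in CL1-0 and orange points for knockdown in CL1-5, and grey bars for the middle 95% of 10000 random lists. The knockdown medians of the interferon (-1.41), inflammatory (-0.79) and hypoxia (-0.68) lists lie furthest from 0, and the hypoxia list lies below its grey bar in both comparisons.

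**Figure D3:**
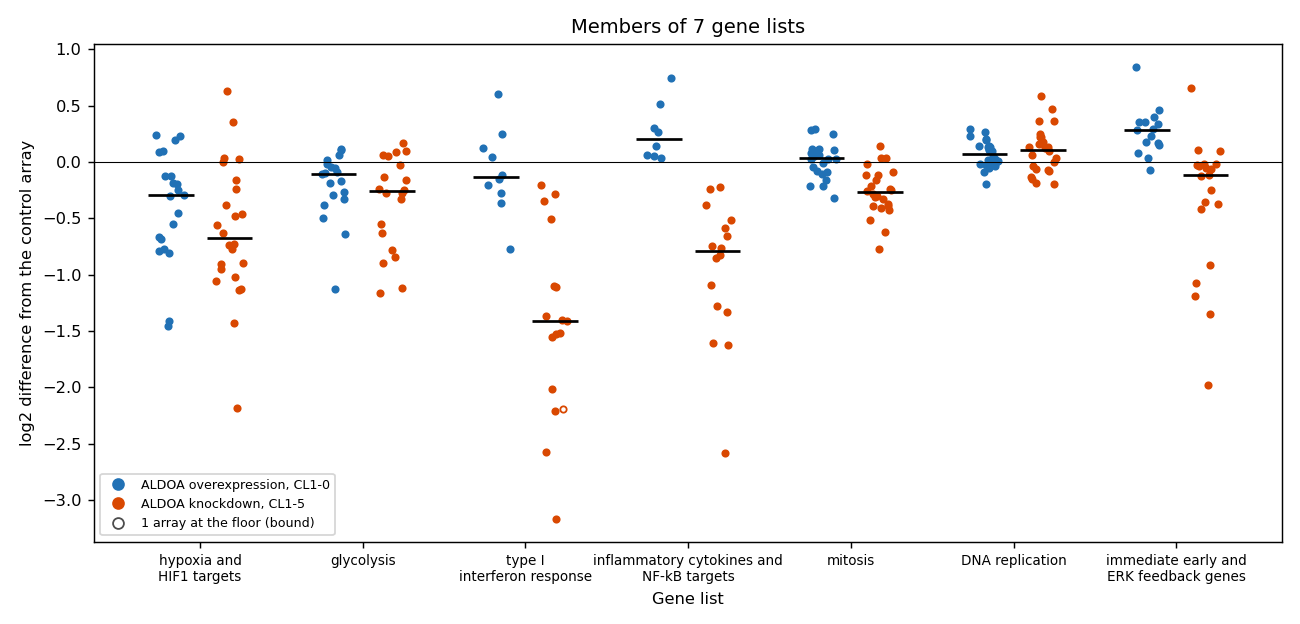
Log2 difference from the control array (vertical axis) of each measured member of 7 gene lists (horizontal axis), with 1 point per gene, black lines at the medians and open points where 1 array was at the floor. All 17 interferon and all 16 inflammatory members lie below 0 in the knockdown comparison.

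Both comparisons together address which genes follow ALDOA, being higher where it was raised and lower where it was reduced, or the reverse. Only IGFBP7, an insulin-like growth factor binding protein (-1.02 with overexpression and 1.01 with knockdown), and HINT3 (-1.14 and 1.17) reached 2-fold in opposite directions, where 0.10 genes would be expected from independent lists. The other HINT3 probe sets gave 0.18 and -0.05 with knockdown. ND6 (1.30 and 1.51) and the glycolytic regulator PFKFB4 (-1.12 and -1.12) reached 2-fold in the same direction, where 0.134 would be expected. The opposite count was 1 under quantile normalization, median scaling and the floor at the 60th percentile, and 0 with the mean of all probe sets. The count in the same direction was 1 with the mean and 5 without the probe sets that can bind several transcripts. Across the 10527 genes measured in both, the differences correlated positively (Pearson r = 0.239, Spearman rho = 0.225), and genes are not independent replicates. Some lists were called on opposite sides with overexpression and knockdown: immediate early and ERK feedback (medians 0.28 and -0.12), inflammatory (0.20 and -0.79) and mesenchymal (-0.17 and 0.22). Hypoxia, glycolysis, fatty acid synthesis and MHC class I lists were lower in both, and the proteasome higher in both. Overexpression calls were lost under 4 settings for the inflammatory list and under 2 for the mesenchymal, MHC class I and proteasome lists.

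Among genes above the floor on all 4 arrays whose measured probe sets pointed the same way in each comparison, those that were higher with more ALDOA in both, ranked by the smaller of their 2 differences, were the cytokine LIF (0.74 with overexpression and -0.83 with knockdown), MGST2 (0.52 and -0.61), TSACC (0.55 and -0.51), ALDOA itself, GSE1 (0.54 and -0.51), APLP1 (0.86 and -0.50), ISYNA1 (0.49 and -0.48), the corepressor BCOR (0.50 and -0.47), LTB (0.42 and -0.96) and RGCC (0.41 and -0.70). At 1.5-fold, a threshold chosen after the data had been seen, 9 genes differed in opposite directions, where 6.78 would be expected from independent lists. ISYNA1 and RGCC lay within 0.02 of 0 when probe sets that can bind several transcripts were left out. Values of that size match the difference between the array floors, so they are read as lost measurements and not as a turned direction. By the same criteria, the genes with the reverse pattern after IGFBP7 were the small GTPase GEM (-0.70 and 1.08), the thrombin receptor F2R (-0.93 and 0.61), the receptor tyrosine kinase AXL (-0.58 and 0.75), IRF8 (-0.69 and 0.55), GPAT3 (-0.64 and 0.53), KBTBD11 (-0.60 and 0.53), PERP (-0.66 and 0.53), VASH2 (-0.55 and 0.53) and FST (-0.52 and 0.57).

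**Figure D4:**
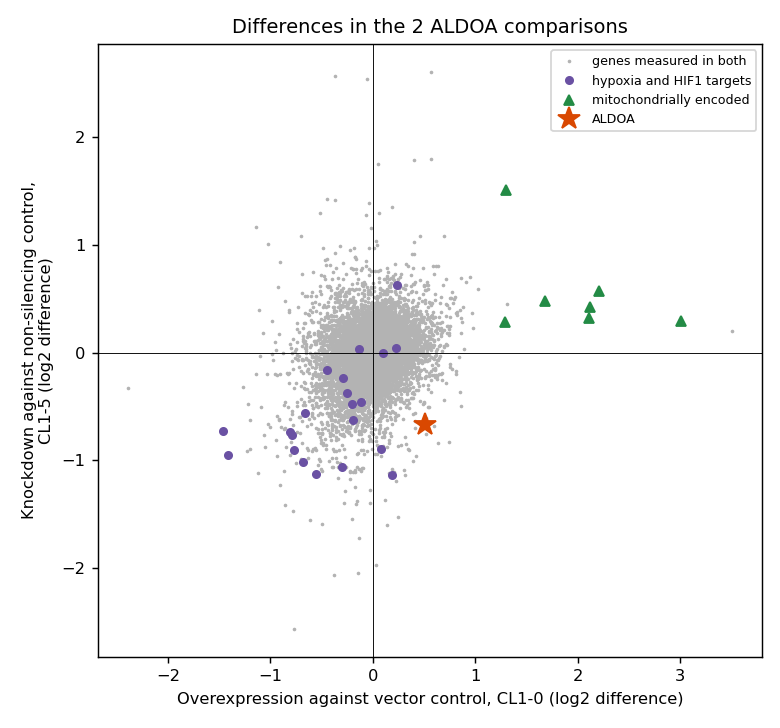
Log2 difference with ALDOA overexpression (horizontal axis) against that with ALDOA knockdown (vertical axis) for the 10527 genes measured in both comparisons, with grey points for all genes, circles for hypoxia and HIF1 targets, triangles for mitochondrially encoded genes and a star for ALDOA. Of the 21 hypoxia targets measured in both, 15 are lower in both, and ALDOA lies at 0.51 and -0.67.

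Several genes tied to hypoxia or invasion were followed in every comparison. HIF1A, the oxygen-regulated transcription factor subunit, was at -0.01 with overexpression and -0.07 with knockdown. VEGFA, an angiogenic HIF1 target, was at 0.08 and -0.90. Its other probe sets gave -0.26 to 0.14 with overexpression and -0.24 to -0.48 with knockdown. MMP9, a gelatinase, was at -0.12 and -0.43. The intermediate filament gene VIM was at -0.10 and 0.13, and MYC was at 0.18 and -0.35. The other VIM probe set, below the floor in the CL1-0 vector control (24.7), gave 0.90 and 1.12. EGFR was at -0.63 and -0.15, with a CL1-0 signal close to the filter (73.7 and 47.5). Its measured probe sets disagreed in direction, from -0.80 to 0.25 with overexpression and from -0.34 to 0.41 with knockdown. CDH1, which encodes E-cadherin, was not measured, since its brightest probe set had signals of 58.2, 26.7, 15.6 and 17.5 on the 4 arrays in the order given above.

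The control arrays of the sublines were compared to describe the cells in which ALDOA was altered. The non-silencing CL1-5 array differed from the CL1-0 vector array in many more genes than either ALDOA comparison, with 1034 at least 2-fold higher and 1158 at least 2-fold lower of 11788 measured, 365 of them with 1 array at the floor. ALDOA was higher in CL1-5 by 0.40 on its brightest probe set. Among genes above the floor on both arrays with agreeing probe sets, those furthest higher in CL1-5 were CDCP1, a transmembrane protein tied to cell adhesion (7.25), the serine protease PRSS23 (6.81), ARHGAP29 (6.63), PRSS3 (6.39), the ERK phosphatase DUSP5 (6.22), BEX1 (6.11), the ectonucleotidase NT5E (5.97), S100A10 (5.86), the cell cycle kinase CDK6 (5.73) and MALL (5.40). Those furthest lower were the phospholipid-binding protein ANXA1 (-7.05), PCDH9 (-5.81), TSPAN12 (-5.68), CCN2, a matricellular protein (-5.55), QPRT (-5.45), ID4 (-5.44), MECOM (-5.34), TPD52L1 (-5.31), SUN3 (-5.20) and the kisspeptin receptor KISS1R (-4.85). Several of these genes had 1 signal just over the floors of 30.9 in CL1-0 and 31.7 in CL1-5. CL1-0 signals were 33 for CDCP1 and 38 for PRSS23 and ARHGAP29, and the CL1-5 signal of MECOM was 38. The sizes and ranks of such genes depend on where the floor is set.

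Of 40 lists placed in the subline comparison, 16 lay above and 2 below the range of random lists, where 2.0 would be expected by chance for independent genes. The S100 and annexin family had a median of 3.08, with 13 of 14 members higher in CL1-5 and S100A6 at least 395-fold higher, whereas ANXA1 was lower. Inflammatory cytokine and NF-kB targets (median 2.59, with 15 of 16 members higher) included CXCL8, at least 114-fold higher, and IL6 (4.60). Type I interferon genes (2.36, with 15 of 18 higher) included IFIT1 (4.08) and OAS3 (3.17). Matrix metalloproteinases (1.48) included MMP1, at least 150-fold higher, and TIMP1 (4.06), and integrins and matrix receptors (1.36) included SDC4 (4.18) and ITGA6 (2.56). Immediate early and ERK feedback genes had a median of 1.30, with DUSP4 at 5.03 and IER3 at 4.99. Hypoxia targets (0.62, NDRG1 3.89, ADM -4.43) and glycolysis genes (0.28, SLC2A1 2.01, SLC2A3 -3.46) were higher on balance. NRF2 targets (0.68), mesenchymal genes (0.58), epithelial genes (0.56), the heat shock response (0.52), MHC class I (0.40), the proteasome (0.35), mitosis (0.29) and the actin cytoskeleton (0.28) were also above the range. Oxidative phosphorylation (-0.29, with 20 of 29 members lower) and MHC class II (-1.29, HLA-DMA -2.21) were below it. HIF1A was higher in CL1-5 by 1.13, VEGFA by 0.96, EGFR by 3.47, VIM by 0.59 and MYC by 0.83.

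The subline and the kind of vector differed together in this comparison and cannot be told apart. The bioB spike-in and 28S ribosomal RNA control signals also differed between the sublines, with a median bioB signal of 528 and 549 on the CL1-0 arrays against 341 and 330 on the CL1-5 arrays, and a 28S ribosomal RNA 5' signal of 1641 and 2197 against 8369 and 6754. Without the probe sets that can bind several transcripts, the metalloproteinase median was 0.21, the hypoxia median 0.22, the actin median 0.04 and the mesenchymal median 0.01, and the mesenchymal median was 0.12 with the floor at the 60th percentile and with no filter and no floor. Mesenchymal genes left the called range under 3 alternative settings, the actin (0.17 with the mean) and MHC class I lists (0.29 and 0.23) under 2, and the hypoxia, oxidative phosphorylation (-0.18), epithelial (0.44), metalloproteinase and mitosis (0.23) lists under 1. With the mean of all probe sets per gene, 758 genes were at least 2-fold lower.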

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

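The counts of unnamed probe sets and the summaries of control signal in this part were chosen after the data had been seen, although the control signals themselves were to be reported from the start. Probe sets without a gene name here were outside the gene comparisons. Of 2042 measured ones, 30 differed at least 2-fold with ALDOA overexpression, 26 higher and 4 lower. Of 1927 measured ones, 32 differed at least 2-fold with ALDOA knockdown, 14 higher and 18 lower. The furthest higher with overexpression had a signal of 1275 in the CL1-0 vector control, 10005 with overexpression, 1472 in the CL1-5 non-silencing control and 1674 with knockdown. The furthest lower with knockdown had a signal of 240 in the non-silencing control and 49 with knockdown.

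Several control probe sets differed between the sublines. The 14 bacterial spike-in probe sets for bioB, bioC and bioD had a median log2 difference of -0.68 between the CL1-5 and CL1-0 arrays. The 4 probe sets for 18S and 28S ribosomal RNA had a median difference of 1.10 in the same sense. The 18S 5' probe set did not separate them, with signals of 7494 and 6491 on the CL1-0 arrays, 10419 in the non-silencing control and 7300 with knockdown. The cre spike-in signals were 14018 and 13821 on the CL1-0 arrays and 13564 and 13580 on the CL1-5 arrays. No explanation was tested for these differences.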

How the results depend on the processing

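The 2 restrictions of the gene set for the correlation were chosen after the data had been seen, and the 8 other alternatives before. ALDOA kept its direction wherever it had a value, from 0.47 to 0.61 with overexpression and from -0.65 to -0.85 with knockdown. It had no value without the probe sets that can bind several transcripts, since all 3 of its probe sets are of that kind. The correlation between the ALDOA comparisons stayed positive, from 0.149 with no filter and no floor to 0.281 without those probe sets, and was 0.274 over bright genes and 0.226 without mitochondrially encoded genes and the hypoxia and glycolysis lists. With overexpression, the 10 genes at least 2-fold higher became 18 with no filter and no floor and 21 without those probe sets. With the mean of all probe sets, the 28 genes lower with overexpression became 6, the 46 higher with knockdown 28, and the 1158 lower in CL1-5 758. The 2 genes in opposite directions became 1 under quantile normalization, 1 under median scaling, 1 with the floor at the 60th percentile and 0 with the mean of all probe sets. The 2 in the same direction became 1 with the mean and 5 without those probe sets. Leaving those probe sets out gave ISYNA1 (-0.02 with overexpression, 0.01 with knockdown), RGCC (-0.02 and 0.01) and NAV2 (0.01 with knockdown) a nominally opposite sign. The mean did so for RGCC with knockdown (0.01). The NAV2 probe sets left lay below the floor on both CL1-5 arrays, so its value sets floor against floor. The other values are of the size of the floor differences, 30.9 against 30.5 in CL1-0 and 31.7 against 31.9 in CL1-5. They are read as lost measurements and not as turned directions. Other values of the genes ranked in each comparison or in both moved by more than the probe-set yardstick in 73 cases and by less in 705. In each of these cases the direction was kept. Genes named only as list members or by the fixed set of always-named genes were not counted here. Among them are genes whose probe sets differ in direction, for example VIM, VEGFA, EGFR and ANKRD37 with overexpression and EGFR with knockdown. The probe sets of PFKFB4 differ in direction with overexpression as well. Of 46 called list medians, 26 were called under all 8 alternatives fixed beforehand, 3 under each of the fewer that left them 5 measured members, and 17 lost the call under at least 1. None of the 46 turned its sign where it was placed. Signal over background limits the dim genes, as 365 of the 2-fold differences between sublines had 1 array at the floor.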

Other observations

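The test of the bright-probe-set trend below was set out before its result was seen. The other tests, of an intensity trend in gene lists, of whether a group follows ALDOA, of ribosomal RNA, of oxygen supply and of the non-silencing vector, and the 1.5-fold counts, were chosen after the result had been seen. Cyclic loess had been set out as the test of an intensity trend. It moved gene differences by a median of 0.02 with overexpression and 0.01 with knockdown, and by at most 0.10 and 0.05. There was thus little trend over all genes for it to remove. Further single genes differed, most of them in lists that as a whole lay inside the random range. In the knockdown array the growth factor TGFA was at -1.21 and the cell cycle inhibitor CDKN1A at -0.79, while p53 targets as a list were within the random range (median -0.13 over 13 members). Within the S100 and annexin family, ANXA1 was at 1.16 and S100A3 at -1.26, and the list median was 0.03. Heat shock genes were lower in 10 of 10 members with a median of -0.07, inside the random range, and HSPB1 was at -0.79. The matrix gene COL6A3 was at -1.06 and the desmosomal gene DSP at -1.18. The helix-loop-helix inhibitor ID2 was at 1.08, beside ID4 at 2.61. Cytosolic ribosomal proteins had medians of -0.02 with overexpression and -0.01 with knockdown, and the TCA cycle list had -0.01 in both.

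Markers of other cell types were mostly below the filter. Leukocyte markers had 1 measured member of 15 with a probe set in CL1-0 and 3 in CL1-5, where LAPTM5 was at -1.25 with knockdown. Endothelial markers had 3 and 4 measured members of 12, basal and squamous markers 1 and 2 of 10. Fibroblast markers had a median of -0.28 over 5 members with overexpression, within the random range, and 3 measured members with knockdown. Neuroendocrine markers had a median of -0.21 over 6 members with knockdown, and alveolar and secretory markers 0.14 over 8 members with overexpression and 0.04 over 8 with knockdown, all within the range. SOX2, a stem cell and squamous lineage factor, had a signal of 8490 in the CL1-0 vector control and lay at the floor in CL1-5, at least 268-fold lower. Cancer testis antigens were within the range in both ALDOA comparisons (-0.01 and -0.12).

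At a threshold of 1.5-fold, 62 genes differed in the same direction in both ALDOA comparisons, where 7.86 would be expected from independent lists, and 9 in opposite directions, where 6.78 would be expected. Of the 62, 50 were lower in both and 12 higher in both, and 8 of the 50 belong to the hypoxia or glycolysis lists.

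Hypoxia and HIF1 targets were lower in both perturbed arrays, although ALDOA was higher in one and lower in the other. Of 21 members measured in both comparisons, 15 were lower in both, 2 were higher in both and 4 differed in direction. A response that follows the amount of ALDOA in both sublines would put the list above the random range with overexpression, whereas its median was -0.29 there. A trend with signal intensity would show in other genes of like signal, but the 100 nearest to each member had median differences of 0.00 with overexpression and 0.01 with knockdown. The random lists were already matched on mean expression, so these neighbours restate that placing and are no separate support. Oxygen supply or density of the cells may have set these genes, and the 15 shared members do not decide it, since they restate the pattern and each group has 1 array, with no word on whether it came from 1 culture or several. An effect of transduction or of ALDOA that differs between sublines also stays open and was not tested.

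Mitochondrially encoded transcripts were higher with overexpression in all 9 probe sets above the floor on every array, from 7 genes, by a median of 2.11 (range 1.23 to 3.01). A trend of bright probe sets would show in nuclear probe sets of like signal, but the 100 nearest to each had a median difference of -0.01. General carry-over of ribosomal RNA would raise the 18S and 28S control probe sets, which had a median of 0.13 (range -0.21 to 0.42), and transcripts that follow ALDOA in both sublines would be lower with knockdown, whereas their median was 0.32 there and 9 of 9 were higher. A difference in mitochondrial content or RNA in the overexpressing cells, or in how their RNA was prepared, may account for it and was not tested.

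Interferon-stimulated genes were lower with knockdown with a list median of -1.41, whereas the 100 other genes nearest in signal to each member had a median difference of 0.01. The random lists were already matched on mean expression, so these neighbours restate that placing. They are no separate support against a trend with intensity. The non-silencing hairpin vector may have induced the interferon genes in the control array. Over the same 17 genes that array had a median of 2.36 above the CL1-0 vector control, and the knockdown array 0.95. MX1 lay at the floor in the CL1-0 vector control and OAS1 in the knockdown array, so some of these differences rest on a floor. The values do not decide whether the vector induced the genes, because the subline differs too. The non-silencing array is also the reference of the knockdown comparison. A list that follows ALDOA would be higher with overexpression, where its median was -0.14 over 10 members, inside the random range of -0.21 to 0.18. Neither explanation can be told apart from the other with these 4 arrays, because the hairpin and its control differ in sequence as well as in ALDOA.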
